A study of Homo sapiens with 12 samples.

How the data were processed

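The data were RNA-seq read counts per gene for 12 libraries of MG63 cells, 3 each for vehicle, 1 µM anticarin-beta for 18 hours, control siRNA and CCT4 siRNA for 2 days. The authors deposited raw counts in 1 table of 50868 genes, not normalized and not pooled over replicates. Per the labels' protocols, libraries were made with a stranded TruSeq kit. Per the submitters' processing notes, STAR 2.5.2a, featureCounts 1.5.0 and Subread were used with the hg38 build. The annotation release, the strand setting of the counting and the handling of reads that map to several places are not given in the sources used here. If strand was not used in counting, reads of genes that overlap on opposite strands would be merged, and genes that share exons on 1 strand can lose or gain reads under either setting, so those named are marked as uncertain. Gene positions and exon overlaps come from GENCODE release 29 on GRCh38, in which 98.5% of the gene identifiers were found.

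Groups and replicate numbers were taken from the labels. Replicates of a group differed by more than sampling noise in every pair (chi-square per degree of freedom from 9.36 to 30.0), so each counted as 1 sample. Totals per library ran from 13393750 to 17492095 counts, at which the floor of 3 counts in 1 library corresponds to 0.172 to 0.224 CPM. Counting intervals and floors cover counting error only.

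Differential expression was tested with edgeR 4.0.16 (R 4.3.3) by its quasi-likelihood test, two-sided, with TMM scaling, filterByExpr on the 4 groups and 1 mean per group over all 12 libraries, which leaves 8 residual degrees of freedom. Every adjusted p-value of a gene is from this test with Benjamini-Hochberg adjustment over the 17717 genes tested, and genes under 0.05 were called. Fold changes carry a prior count of 0.125, and standard errors were derived from the F statistic. Values in CPM are scaled by TMM. A gene with 0 counts in a group is given as a bound against 3 counts over that group, and a gene with 1 to 3 counts as a ratio with its 95% counting interval. The interval of the CCT4 change used the t distribution with the degrees of freedom of the fit.

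The difference of the responses was tested as a contrast in the same fit. Shared calls were counted beside the number expected from independent lists. Gene sets were 33 lists with 760 symbols, all of them in the table and 46 of these through an older symbol, tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of a contrast, and again with an estimated correlation. Members were counted over all genes tested and adjusted over the list alone. Some lists share genes, such as JUNB in the immediate-early and STAT3 lists and BBC3 in the apoptosis and p53 lists. Lists that pass are therefore not independent findings.

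The groups, tests, gene lists, alternatives and the rule for naming genes were chosen before the data were examined. The rule took CCT4, the 8 highest and 8 lowest log2 fold changes per comparison among called genes with a mean of at least 5 CPM in the higher group, a proper symbol and no overlap between the groups. It added 2 to 4 members with the smallest p of each list described together with CCT subunits, HSPA5, HSPA1A, DDIT3, CDKN1A and MKI67. For the joint comparison it took, under the same limits, 5 genes higher in both, 5 lower in both and 5 opposite in each direction. A few genes that the rule takes are not reported here. By chance alone 10% of genes have 3 against 3 values that do not overlap.

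Alternatives were RLE, upper-quartile and library-total scaling, DESeq2 1.42.0, limma-voom, other low-count filters, each experiment alone, a replicate block, a 2-fold threshold, a stricter threshold and the omission of each library. Added after seeing the data were the omission of mitochondrially encoded genes, the omission of genes with unstable counts, and the removal of GC and length trends from the correlation.

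The tests were tried on simulated counts drawn from the real means and library sizes, with a small seeded set of genes changed, in turn up and down. All other genes had the same mean in every group, and the spread followed its trend with level. For the compound comparison over 17152 genes, edgeR recovered 27.7% of 65 genes changed 1.5-fold, 71.9% of 64 at 2-fold and 90.8% of 65 at 4-fold, with 3.15% of its calls false. For the siRNA comparison over 17123 genes the shares were 27.7%, 83.1% and 87.7% of 65 genes each, with 3.73% false. DESeq2 gave 11.3% and 11.6% false calls in these draws, above its nominal level, and limma-voom 4.62% and 5.15%. Camera found a list built only from raised genes and not a list of unchanged ones, an outcome that this design makes easy. The real compound comparison called 73.0% of genes, so the shares above need not hold for it.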

Results

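RNA from MG63 cells, an established human osteosarcoma line, was sequenced in 12 libraries that fall into 4 groups of 3. In the compound experiment, cells received 1 µM anticarin-beta or its vehicle and were collected after 18 hours. In the siRNA experiment, cells were transfected with a control siRNA or with an siRNA against CCT4, a subunit of the cytosolic chaperonin that folds actin and tubulin, and were collected after 2 days. The series title asks which genes respond to the compound, and its design names the CCT4 knockdown as the other treatment. Library totals ranged from 13393750 to 17492095 counts. The labels do not say that the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

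CCT4 itself was examined first, as the gene targeted by the siRNA. Its mRNA was not lower in the libraries labelled CCT4 siRNA: the level was 206 ± 9.18 CPM against 177 ± 14.4 CPM with control siRNA (SD, n = 3 each), a log2 fold change of 0.22 ± 0.09 (SE; adjusted p = 0.129). The 95% interval of the fold ran from 1.01 to 1.34, and under library totals alone the log2 fold change was 0.09 with a 95% interval from −0.13 to 0.30. Adjusted over the 9 chaperonin subunit genes alone, the increase under TMM scaling passed the threshold. The knockdown named by the labels is therefore not seen at the mRNA level, and every direction given for this comparison is that of the libraries labelled CCT4 siRNA. With anticarin-beta, in contrast, CCT4 mRNA fell from 236 ± 22.9 to 82.3 ± 8.49 CPM (SD, n = 3 each), 2.87-fold lower (log2 fold change −1.52 ± 0.10, adjusted p = 1.8e-08). The difference between the 2 changes was −1.74 on the log2 scale (adjusted p = 2.8e-07). CCT4 (ENSG00000115484) lies on the minus strand of chromosome 2 at 61868089 to 61888804 in GRCh38, and an exon of a gene on the opposite strand overlaps it; the strand setting of the counting is not given in the sources used here, so reads of that gene may be counted with it.

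**Figure D1:**
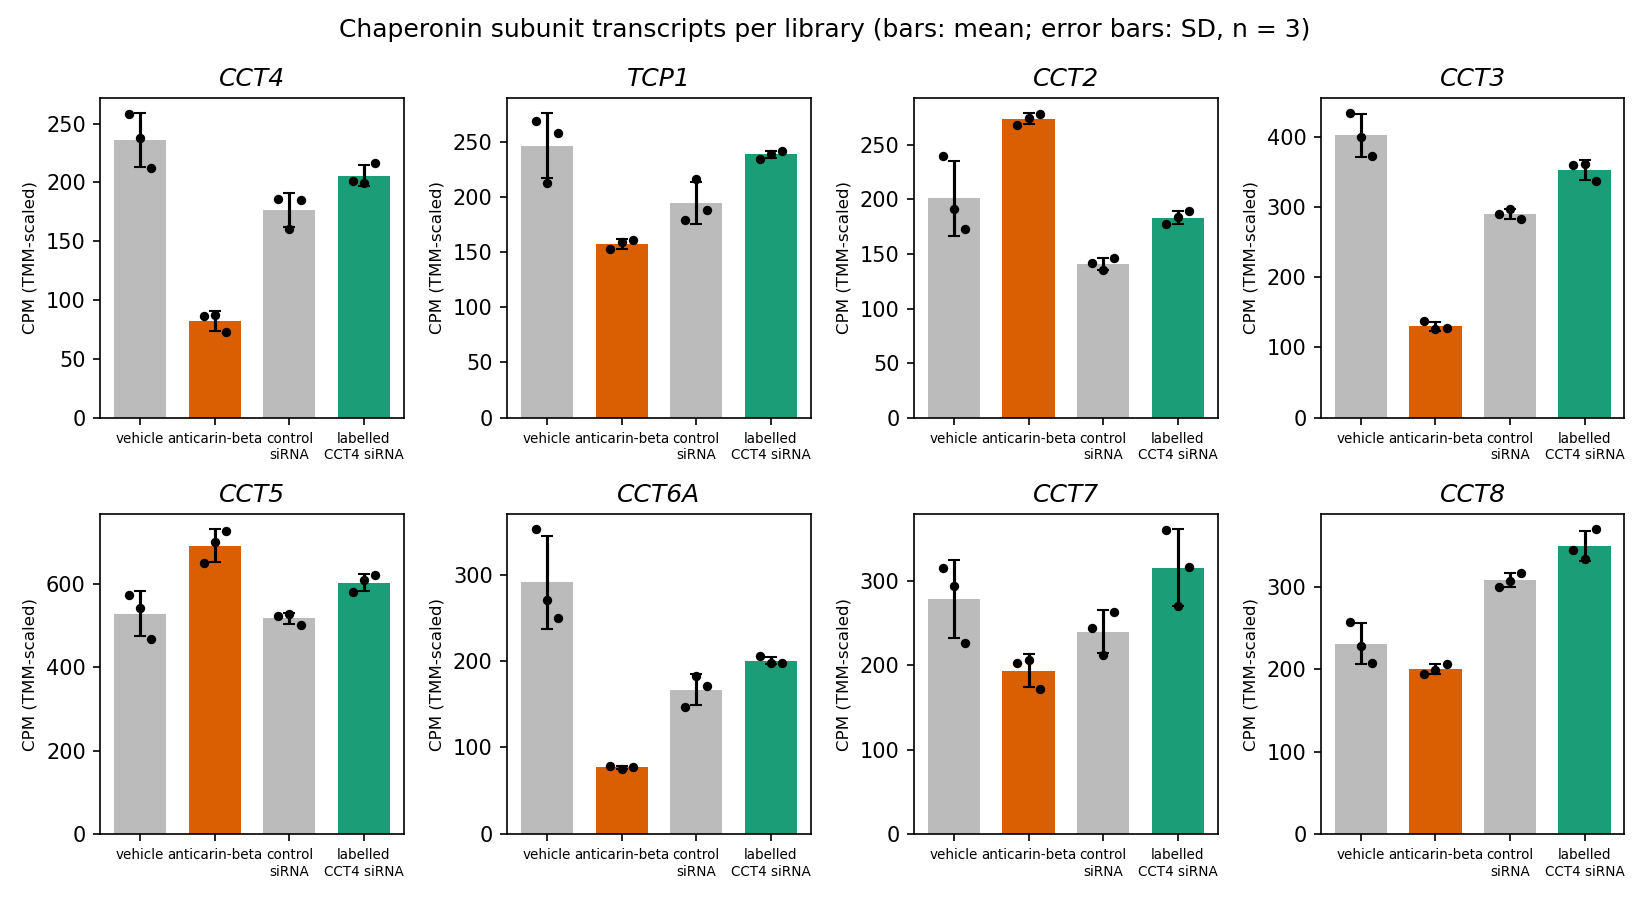
TMM-scaled CPM of 8 chaperonin subunit genes (y axes, from 0) in each library; bars are group means, error bars the SD and points the 3 libraries of a group. CCT4 averages 82.3 CPM with anticarin-beta against 236 with vehicle, and 206 CPM in the libraries labelled CCT4 siRNA against 177 with control siRNA.

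The other chaperonin subunits did not move as one block with anticarin-beta. Of 9 subunit genes, 7 were lower and 2 higher, over all genes tested and adjusted over the list alone. The largest decreases were in CCT6A (3.77-fold lower, log2 fold change −1.92 ± 0.12), CCT3 (3.08-fold, −1.62 ± 0.07) and CCT4, while CCT7 was 1.44-fold lower and TCP1, which shares exons with another gene on its strand, 1.56-fold lower. CCT2 (log2 fold change 0.45 ± 0.10) and CCT5 (0.39 ± 0.08) were higher, but with library totals alone CCT2 missed the threshold and CCT5 turned to −0.03. The call of CCT8 (−0.21 ± 0.08) was lost without vehicle replicate 1 (−0.13) or anticarin-beta replicate 1 (−0.19) or 2 (−0.21). That of the low-count CCT6B (−1.40 ± 0.52) was lost without vehicle replicate 2 (−1.30) or 3 (−1.09) or any 1 anticarin-beta library (−1.43, −1.35 and −1.43). As a set the subunits missed the threshold (median −0.65, camera adjusted p = 0.0871, and adjusted p = 0.509 with an estimated correlation), but passed with a replicate block (camera adjusted p = 0.0450). In the libraries labelled CCT4 siRNA, 3 subunits (TCP1, CCT2 and CCT3) were higher and 0 lower. Adjusted over the list alone these were 8 and 0, with CCT4 itself among the 8. The median was 0.26 (adjusted p = 0.0150, but adjusted p = 0.219 with an estimated correlation), and 0 subunits passed with library totals alone. TCP1 (0.29 ± 0.09) was lost without control siRNA replicate 1 (0.24) or 3 (0.27), anticarin-beta replicate 2 (0.30) or any 1 of the libraries labelled CCT4 siRNA (0.31, 0.29 and 0.29). CCT2 (0.38 ± 0.10) was lost without control siRNA replicate 1 (0.38) or 2 (0.35) or CCT4 siRNA replicate 2 (0.38) or 3 (0.36), and CCT3 (0.28 ± 0.07) without CCT4 siRNA replicate 2 (0.27).

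Anticarin-beta changed most of the transcriptome. Of 17717 genes tested, 12926 passed (73.0%), 6186 higher and 6740 lower than with vehicle, and 8101 of them by more than 2-fold. PNLIPRP3, a member of the pancreatic lipase family on chromosome 10 (116427867 to 116477957), went from 0 counts in the vehicle libraries to 17.7 ± 1.44 CPM (SD, n = 3), at least 319-fold higher against a floor of 3 counts over the group. The non-coding LINC01173 was likewise at least 90.4-fold higher. TSLP, an epithelial cytokine, rose 121-fold (log2 fold change 6.92 ± 0.27, adjusted p = 2.15e-10). HRK, a pro-apoptotic BH3-only gene, and ANKRD1, a target of YAP signalling, had 1 count each over the vehicle libraries, so their ratios of 874 (95% counting interval 156 to 34580) and 647 (115 to 25596) are loose. The same holds for SLAMF7 (326, from 89.8 to 2704), ST14 (178, from 48.6 to 1475) and SLC8A2 (117, from 39.5 to 571).

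The steepest decreases with the compound included HENMT1, an RNA methyltransferase gene with 0 counts in the treated libraries and at least 90.1-fold lower. MRPS26, a mitochondrial ribosomal protein gene, was 67.1-fold lower (log2 fold change −6.07 ± 0.31, and −7.29 without anticarin-beta replicate 1). SOX18, a transcription factor gene, had 3 counts left over the treated libraries (ratio 105, from 35.7 to 511). CSRP2BP, ZNF18 and CEBPA-AS1 had 2, 1 and 2 counts over the treated libraries, with ratios of 282 (from 78.0 to 2336), 214 (from 38.2 to 8493) and 88.6 (from 24.3 to 735). PCDHGC5 was also among the lowest (−7.49 ± 1.82), but it had 38, 1306 and 29 counts in the vehicle libraries, so its place rests on vehicle replicate 2. Its log2 fold change was −3.59 without that library and −8.16 without anticarin-beta replicate 1, and its call was lost with limma-voom. All 4 of these share exons with another gene on the same strand and are uncertain.

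Genes that cells switch on within minutes to hours of a stimulus were higher with anticarin-beta almost without exception. Of 27 immediate-early genes 24 were higher and 0 lower, with a median log2 fold change of 2.66. JUN, an AP-1 subunit on chromosome 1 (58780788 to 58784327), rose 18.5-fold (log2 fold change 4.21 ± 0.08, adjusted p = 1.24e-12), FOSL1 9.94-fold, IER5 6.28-fold and KLF10 5.10-fold. Of 18 feedback genes of the MAPK pathway 17 were higher and 0 lower (median 2.87), among them SPRY2 (15.9-fold), DUSP5 (14.4-fold), DUSP6 (8.01-fold) and SPRY4 (7.01-fold), which restrain receptor and ERK signalling. Of 22 inflammatory targets of NF-kB 20 were higher and 0 lower (median 2.57), with LIF 11.8-fold, TNFAIP3 5.65-fold, NFKB2 5.11-fold and ICAM1 4.33-fold higher. The counts were the same adjusted over the list alone, and the camera adjusted p-values of 8.19e-15, 1.09e-14 and 3.13e-19 became adjusted p = 0.00497, 0.00181 and 0.0196 with an estimated correlation.

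Stress and cell death genes rose in larger part than they fell. Among 26 genes of the integrated stress response, 18 were higher and 6 lower (median 1.37, adjusted p = 7.4e-06, and adjusted p = 0.020 with an estimated correlation): PPP1R15A, which directs eIF2-alpha dephosphorylation, rose 16.8-fold, NUPR1 6.94-fold, SLC7A1 4.36-fold and ATF4 2.68-fold. DDIT3, the gene of the stress factor CHOP, was 2.98-fold higher, though it shares exons with another gene on its strand. Of 26 apoptosis regulators 15 were higher and 4 lower (median 0.64, adjusted p = 0.0011, and adjusted p = 0.020 with an estimated correlation). The members with the smallest p act on both sides of cell death: PMAIP1 (7.00-fold higher), TNFRSF10B (3.05-fold) and BBC3 promote it, whereas MCL1 (5.09-fold) and BCL2L1 (3.76-fold) oppose it. BBC3 (3.86-fold higher) and MCL1 share exons with another gene on their strand. Of 23 p53 targets 12 were higher and 6 lower (median 0.78, adjusted p = 0.00496, and adjusted p = 0.0315 with an estimated correlation), with GADD45A 28.4-fold, AEN 8.64-fold and CDKN1A 2.12-fold higher. Counts adjusted over the list alone did not differ for these 3 lists. Scaled by library totals alone, 15, 10 and 12 genes of the stress, apoptosis and p53 lists were higher and 7, 6 and 6 lower.

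The heat shock genes did not rise together. Of 24 genes controlled by HSF1, 8 were higher and 13 lower, also when adjusted over the list alone (median −0.36, adjusted p = 0.72), or 5 and 15 with library totals alone. HSPA8, the constitutive cytosolic HSP70, was 4.08-fold lower and HSPA1A 2.01-fold lower, whereas HSPB8 (2.44-fold) and HSPA4 (2.37-fold) were higher. HSPA8 shares exons with another gene on the same strand. In the ER chaperone list of 22 genes, 10 were higher and 5 lower, also when adjusted over the list alone (median 0.17, adjusted p = 0.549); with library totals alone the median was −0.25, with 5 higher and 11 lower. HSPA5, the ER HSP70, was 1.58-fold higher (log2 fold change 0.66 ± 0.10).

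DNA replication genes fell as a group. Of 34 genes 33 were lower and 0 higher, over all genes and adjusted over the list alone, with a median log2 fold change of −1.88 (camera adjusted p = 1.0e-16, and adjusted p = 0.0034 with an estimated correlation). RRM2, a ribonucleotide reductase subunit that shares exons on its strand, was 6.75-fold lower, RFC4 6.42-fold, LIG1 5.93-fold and MCM4, part of the replicative helicase, 4.16-fold lower. Of 30 mitosis genes 12 were lower and 6 higher (11 and 5 adjusted over the list alone; adjusted p = 0.45), or 20 and 1 with library totals alone (median −0.49), with CCNA2 2.94-fold and TOP2A 2.02-fold lower. Without vehicle replicate 1, the library that stood farthest from its group, 10 mitosis genes were lower and 11 higher, and the median went from −0.07 to 0.02. MKI67, a proliferation marker, differed by 0.21 ± 0.42 (log2, adjusted p = 0.67). Its levels ran from 108 to 268 CPM among the vehicle libraries and from 164 to 267 CPM with anticarin-beta. They also varied 2.97-fold among the libraries labelled CCT4 siRNA, so its counts are unstable and leave a change or none open.

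The 22 replication-dependent histone genes went the other way: 21 were higher and 0 lower, also when adjusted over the list alone (median 2.74, adjusted p = 9.6e-10, and adjusted p = 0.0018 with an estimated correlation). HIST1H4H rose 41.2-fold and HIST1H2BG 40.4-fold, from low levels of 1.70 to 2.77 and 0.96 to 1.55 CPM in the vehicle libraries. Histone genes are near-identical in sequence and the handling of reads that map to several places is not given, so single members are uncertain.

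Transcripts encoded on the mitochondrial genome fell throughout. All 13 were lower with anticarin-beta, also when adjusted over the list alone (median −2.15, adjusted p = 2.35e-17, and adjusted p = 0.0315 with an estimated correlation); MT-ND3 was 10.1-fold, MT-ND5 5.49-fold and MT-CYB 4.10-fold lower. Their share of all counts was 4.87% ± 0.20 with vehicle and 1.27% ± 0.10 with the compound (SD, n = 3 each). Of 31 respiratory chain genes of the nucleus 16 were lower and 5 higher, also when adjusted over the list alone (median −0.28, adjusted p = 0.11), or 25 and 1 with library totals alone.

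Proteasome subunits were mostly lower with the compound, 25 of 31 against 3 higher, also when adjusted over the list alone (median −0.59, adjusted p = 0.0057, but adjusted p = 0.51 with an estimated correlation). PSMD4 was 3.06-fold and PSMD2 2.33-fold lower, and PSMC5 fell by 1.32 on the log2 scale. Of 31 matrix genes 22 were higher and 1 lower, also when adjusted over the list alone (median 0.53, adjusted p = 0.0029, but adjusted p = 0.56 with an estimated correlation); with library totals alone 12 were higher and 8 lower. THBS1, a matricellular glycoprotein, rose 15.5-fold and COL12A1 3.71-fold. Of 18 metalloproteinase and invasion genes 12 were higher and 2 lower, also when adjusted over the list alone (median 0.98, adjusted p = 8.1e-04, and adjusted p = 0.041 with an estimated correlation), led in size by MMP3, a matrix protease (49.3-fold), and ADAMTS1 (4.20-fold). Among 18 cation pump and transporter genes 14 were higher and 2 lower, also when adjusted over the list alone (median 0.72, adjusted p = 0.037, but adjusted p = 0.18 with an estimated correlation); ATP1B1, a subunit of the sodium pump, rose 4.07-fold. Among the invasion genes 11 were higher and 5 lower with library totals alone, and among the pump and transporter genes 9 and 3.

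Of the 33 lists, 13 passed in this comparison and 10 of them held with an estimated correlation. The scaling sets where no change lies: the median log2 fold change of all genes was −0.06 with TMM, −0.18 with upper-quartile scaling and −0.48 with library totals alone, where 4292 genes were higher and 8959 lower.

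**Figure D2:**
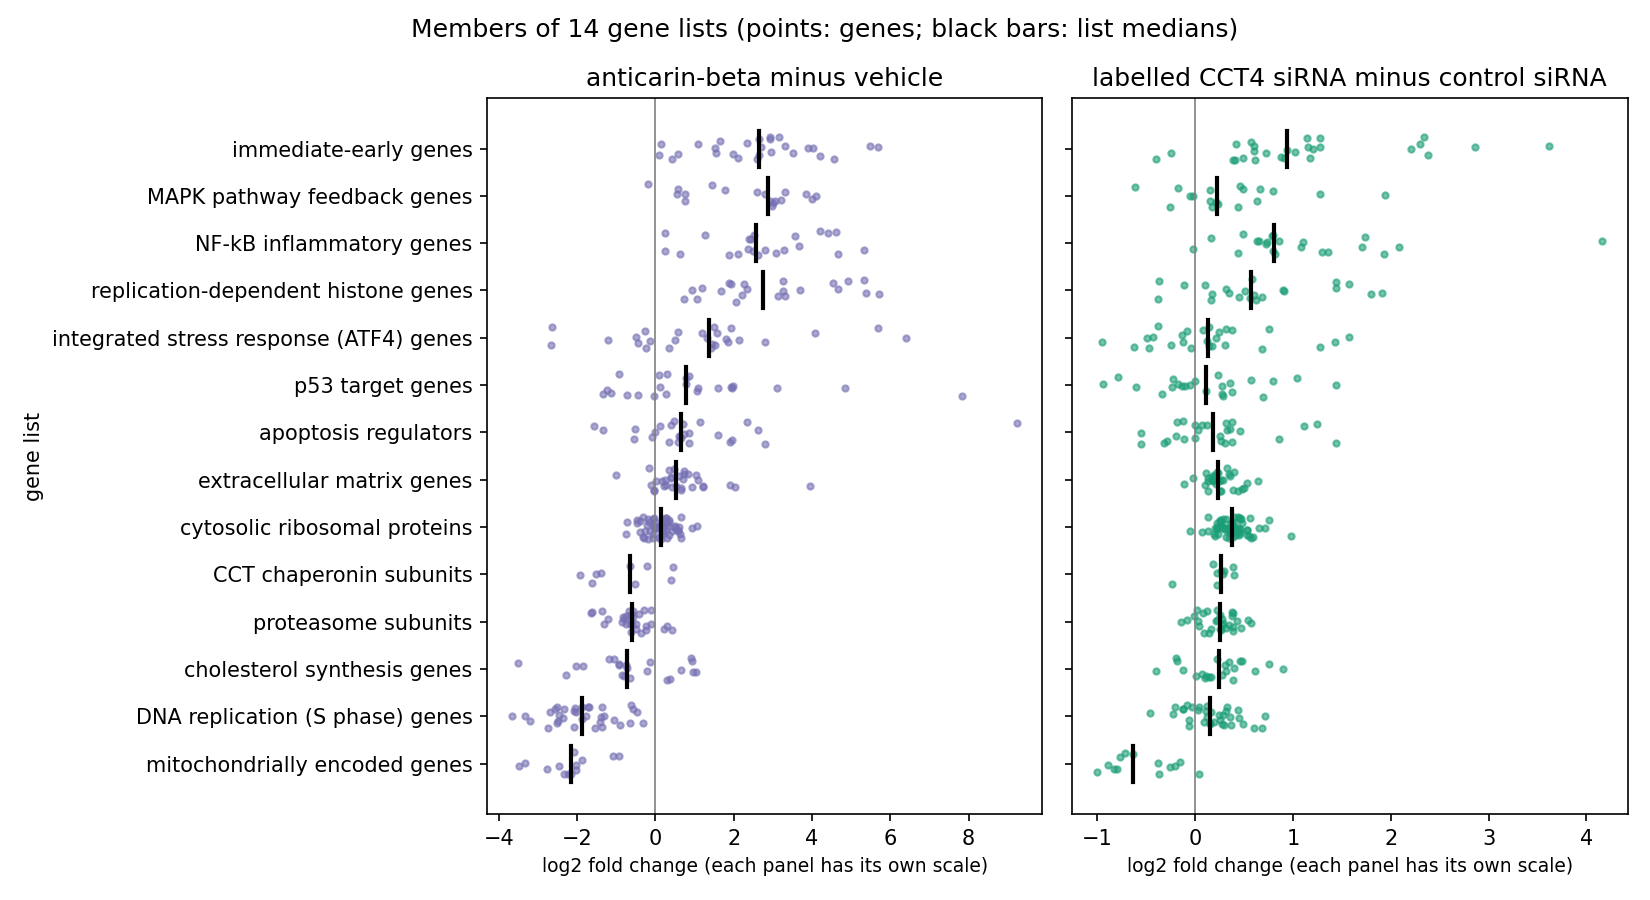
Log2 fold changes of the members of 14 gene lists (points, 1 per gene) and the list medians (black bars), for anticarin-beta minus vehicle (left) and the libraries labelled CCT4 siRNA minus control siRNA (right); the x axes differ in scale. DNA replication genes have a median of −1.88 on the left and 0.16 on the right, and immediate-early genes 2.66 and 0.94.

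The comparison of the libraries labelled CCT4 siRNA with control siRNA, in which CCT4 mRNA was not lower, gave fewer and smaller changes. Of 17717 genes 3493 passed, 1892 higher and 1601 lower, and 543 of them changed more than 2-fold. The neutrophil chemokine gene CXCL2, on chromosome 4 (74097035 to 74099293), rose 17.9-fold from 13.7 ± 0.132 to 245 ± 7.81 CPM (SD, n = 3 each; log2 fold change 4.16 ± 0.13, adjusted p = 2.65e-09). EGR1, an immediate-early transcription factor gene, rose 12.3-fold (3.62 ± 0.18), EGR3 5.21-fold, JUN 5.05-fold and JUNB 4.93-fold. EFCAB12, EFNA1 and LINC00641 complete the 8 highest, at 4.91-fold, 4.77-fold and 4.70-fold.

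The lowest in the libraries labelled CCT4 siRNA was RDH10, a retinol dehydrogenase gene on chromosome 8 (73294612 to 73325281), 3.14-fold lower (198 ± 10.3 to 63.0 ± 1.15 CPM, log2 fold change −1.65 ± 0.09, adjusted p = 5.53e-07). ASB13 was 2.85-fold, PALB2, a partner of BRCA2, 2.77-fold, PARS2 2.68-fold, ZNF550 2.62-fold and GALNT15 2.58-fold lower. ZNF436-AS1 (2.64-fold) and AGGF1 (2.60-fold) share exons with another gene on their strand.

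Immediate-early genes had the largest list median in the libraries labelled CCT4 siRNA: 21 of 27 were higher and 0 lower, or 22 and 0 adjusted over the list alone (median 0.94, camera adjusted p = 8.0e-41, and adjusted p = 6.2e-04 with an estimated correlation). Of 22 inflammatory NF-kB targets 19 were higher and 0 lower, or 20 and 0 adjusted over the list alone (median 0.81, adjusted p = 1.9e-49, and adjusted p = 0.0035 with an estimated correlation), with TNFAIP3 3.80-fold, CXCL3 3.33-fold and CXCL1 3.27-fold higher. Of 18 MAPK feedback genes 7 were higher and 1 lower, or 8 and 1 adjusted over the list alone (median 0.23, adjusted p = 2.2e-05, and adjusted p = 0.020 with an estimated correlation); MAFF rose 3.84-fold. Of 18 STAT3 targets 8 were higher and 1 lower, or 11 and 1 adjusted over the list alone (median 0.21, adjusted p = 5.8e-08, and adjusted p = 0.0035 with an estimated correlation), among them CEBPD (1.88-fold), SOCS3 (1.61-fold) and BCL3 (1.86-fold), which shares exons on its strand. The counts were 7 higher and 3 lower for MAPK feedback genes and 6 and 3 for STAT3 targets with library totals alone.

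Ribosomal protein genes rose together but by little: 41 of 59 were higher and 0 lower, or 49 and 0 adjusted over the list alone (median 0.38, adjusted p = 9.2e-17, and adjusted p = 0.041 with an estimated correlation). RPL30 rose 1.37-fold and RPL24 1.44-fold in these labelled libraries. With library totals alone 23 were higher and 0 lower. Of 22 cholesterol synthesis genes 6 were higher and 0 lower, or 9 and 1 adjusted over the list alone (median 0.25, adjusted p = 0.0012, and adjusted p = 0.039 with an estimated correlation), with HMGCS1, which makes the mevalonate precursor HMG-CoA, 1.86-fold higher. Of 22 histone genes 11 were higher and 0 lower, or 13 and 0 adjusted over the list alone (median 0.57, adjusted p = 3.8e-06, and adjusted p = 0.0050 with an estimated correlation). Of 26 apoptosis regulators 6 were higher and 1 lower, the same adjusted over the list alone (median 0.19, adjusted p = 0.0049, and adjusted p = 0.041 with an estimated correlation); PMAIP1 rose 2.17-fold and BBC3, which shares exons on its strand, 2.71-fold. Of the cholesterol, histone and apoptosis genes 3, 8 and 4 were higher and 1, 0 and 3 lower with library totals alone, where the apoptosis median was 0.06.

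Mitochondrially encoded transcripts were lower here too, 11 of 13 with 0 higher, also when adjusted over the list alone (median −0.64, adjusted p = 1.0e-13, but adjusted p = 0.067 with an estimated correlation). MT-CO2 was 1.85-fold lower, and the share of counts fell from 2.20% ± 0.11 to 1.24% ± 0.01 (SD, n = 3 each) in the libraries labelled CCT4 siRNA. Proteasome subunits were higher, 12 of 31 with 0 lower, or 16 and 0 adjusted over the list alone (median 0.26, adjusted p = 1.1e-04, but adjusted p = 0.22 with an estimated correlation); PSMA7 rose 1.48-fold. With library totals alone 3 subunits were higher and 0 lower. Of 34 DNA replication genes 8 were higher and 1 lower, or 9 and 1 adjusted over the list alone (median 0.16, adjusted p = 0.015, but adjusted p = 0.16 with an estimated correlation), with E2F1 1.40-fold higher; with library totals alone 4 were higher and 3 lower. Of 26 integrated stress response genes 9 were higher and 2 lower, or 10 and 4 adjusted over the list alone (median 0.13, adjusted p = 0.0051, but adjusted p = 0.10 with an estimated correlation); PPP1R15A rose 2.97-fold and GDF15, a stress-induced cytokine gene, 2.69-fold. With library totals alone 5 of these were higher and 7 lower. DDIT3 differed by −0.43 ± 0.21 and CDKN1A by 0.27 ± 0.14 (log2, adjusted p = 0.18 and 0.19).

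None of the remaining lists that passed in the libraries labelled CCT4 siRNA held with an estimated correlation. Of 31 matrix genes 12 were higher and 0 lower, or 16 and 0 adjusted over the list alone (median 0.24, adjusted p = 2.07e-05, but adjusted p = 0.296 with an estimated correlation). Of 26 hypoxia and glycolysis genes 10 were higher and 1 lower, or 11 and 1 adjusted over the list alone (adjusted p = 0.000121, and adjusted p = 0.213 with an estimated correlation). Of 31 nuclear respiratory chain genes 11 were higher and 1 lower, or 13 and 1 adjusted over the list alone (adjusted p = 9.63e-05, and adjusted p = 0.132 with an estimated correlation). Of 18 metalloproteinase and invasion genes 5 were higher and 0 lower, the same adjusted over the list alone (adjusted p = 0.00512, and adjusted p = 0.105 with an estimated correlation); MMP3 rose 3.03-fold. Of 18 cation pump genes 5 were higher and 1 lower, or 8 and 1 adjusted over the list alone (adjusted p = 0.00442, and adjusted p = 0.0998 with an estimated correlation). Actin genes (6 of 19 higher, 0 lower; 8 and 0 adjusted over the list alone), tubulin genes (5 of 15 and 0 on both counts), prefoldin and cofactor genes (4 of 14 and 1; 5 and 1) and osteoblast genes (5 of 12 and 1; 6 and 2) had adjusted p = 0.0107, 0.0281, 0.0437 and 0.0349, and adjusted p = 0.0998, 0.160, 0.184 and 0.296 with an estimated correlation. Fewer members of these lists were higher with library totals alone: 5 matrix genes (0 lower), 5 hypoxia (1), 5 respiratory chain (1), 4 invasion (1), 3 cation pump (1), 3 actin (0), 3 tubulin (0), 2 prefoldin (1) and 4 osteoblast genes (2).

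In all, 22 of the 33 lists passed in the labelled CCT4 siRNA libraries and 8 held with an estimated correlation, though some of these lists share genes. The number of genes called fell with the omission of any 1 library of the siRNA groups, not of a particular one. It was 2207, 2202 and 2612 without control siRNA replicate 1, 2 or 3, and 2274, 2223 and 2296 without CCT4 siRNA replicate 1, 2 or 3. With library totals alone 902 genes were higher and 2800 lower, and the median of all genes moved from 0.01 to −0.12.

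The 2 responses were then set side by side; the comparisons share no control library. Of the genes called, 1197 were higher in both, against 661 if the lists were independent, and 1045 were lower in both, against 609. Genes were ranked among those with a proper symbol, a mean of at least 5 CPM in each higher group and no overlap between groups. Within these limits CXCL2, EGR1, JUN, EFCAB12 and LINC00641 were the 5 genes higher in both with the largest smaller change. With anticarin-beta they rose 9.68-fold, 7.63-fold, 18.5-fold, 22.3-fold and 11.8-fold. RDH10, ASB13, PALB2, PARS2 and ZNF436-AS1 were the 5 lower in both, by 10.1-fold, 55.6-fold, 5.48-fold, 5.67-fold and 4.84-fold with the compound; for ASB13 the log2 fold change was −5.80, and −7.05 without anticarin-beta replicate 1. Same-direction genes came to 2242 of the 3493 called in the libraries labelled CCT4 siRNA (64.2%), and opposite ones to 659, against 1279 if independent. Without any 1 library of the siRNA groups, 1480 to 1646 genes were shared in direction. Across genes, which are not independent replicates, the log2 fold changes correlated with Pearson r = 0.33 and Spearman rho = 0.33, and with r = 0.14 without a low-count filter.

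Some genes went opposite ways. TUFT1 was 11.8-fold higher with anticarin-beta and fell by 0.59 on the log2 scale in the libraries labelled CCT4 siRNA (difference of log2 fold changes 4.15, adjusted p = 7.52e-11), and PKP2, a desmosome gene, 7.14-fold higher and 1.67-fold lower. BRIX1 (7.91-fold higher and 1.31-fold lower, −0.39 ± 0.10) lost its second call without control siRNA replicate 1 (−0.39) or 2 (−0.38) or CCT4 siRNA replicate 1 (−0.37) or 2 (−0.35). KCNJ2 (9.93-fold higher and 1.38-fold lower, −0.46 ± 0.15) lost it without any 1 control siRNA or anticarin-beta library, vehicle replicate 2 or CCT4 siRNA replicate 1 or 2, with values from −0.48 to −0.40. NIPA1, 5.94-fold higher and 2.31-fold lower, shares exons on its strand. MSC, a transcription factor gene, was 9.53-fold lower with the compound and 2.35-fold higher in the libraries labelled CCT4 siRNA (difference −4.49, adjusted p = 1.43e-09), and DRAXIN 5.93-fold lower and 1.84-fold higher. RRM2 and RNASEH2A, both needed for DNA synthesis or repair, were 6.75-fold and 10.4-fold lower with the compound and 1.35-fold and 1.28-fold higher in the labelled libraries, though both share exons on their strand. KCNJ12 was 12.1-fold lower and 1.58-fold higher (0.66 ± 0.21), the second call being lost without vehicle replicate 2 or 3, anticarin-beta replicate 1 or 2, any 1 control siRNA library or CCT4 siRNA replicate 2 or 3, with values from 0.44 to 0.69.

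The test of the difference between the responses called 10610 genes, 4866 with a higher and 5744 with a lower value for the compound; 3724 and 7283 with library totals alone. Of the 33 lists 16 differed and 4 held with an estimated correlation: DNA replication genes (33 of 34 lower for the compound, median −2.03), MAPK feedback genes (15 of 18 higher, 2.01), histone genes (18 of 22 higher, 2.15) and integrated stress response genes (17 of 26 higher, 1.17). Counts adjusted over the list alone were the same for these 4. The 2 experiments differ in agent, delivery and duration, which cannot be separated here. Starting levels differed too: SPRY2, DUSP5, DUSP6 and SPRY4 were all higher with control siRNA than with vehicle. DUSP6 stood at 109 to 113 CPM against 11.9 to 12.5 CPM. It ended at 92.9 to 108 CPM with anticarin-beta and 121 to 127 CPM in the libraries labelled CCT4 siRNA. SPRY2 ended higher with the compound (65.2 to 76.0 against 25.6 to 28.1 CPM). The NF-kB targets LIF, TNFAIP3, NFKB2, ICAM1, CXCL1 and CXCL3 were also higher with control siRNA than with vehicle. So were the interferon-stimulated genes CMPK2 and MX1. TNFAIP3 stood at 222 to 228 CPM against 12.3 to 15.1 CPM, and MX1 at 378 to 401 CPM against 115 to 198 CPM. Fold changes of such genes thus start from unlike levels in the 2 experiments. The lists as a whole were not compared in this way. JUNB rose less with the compound than in the labelled CCT4 siRNA libraries (difference −1.72, adjusted p = 2.39e-08), in contrast to JUN, which rose more (difference 1.87, adjusted p = 9.32e-09).

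**Figure D3:**
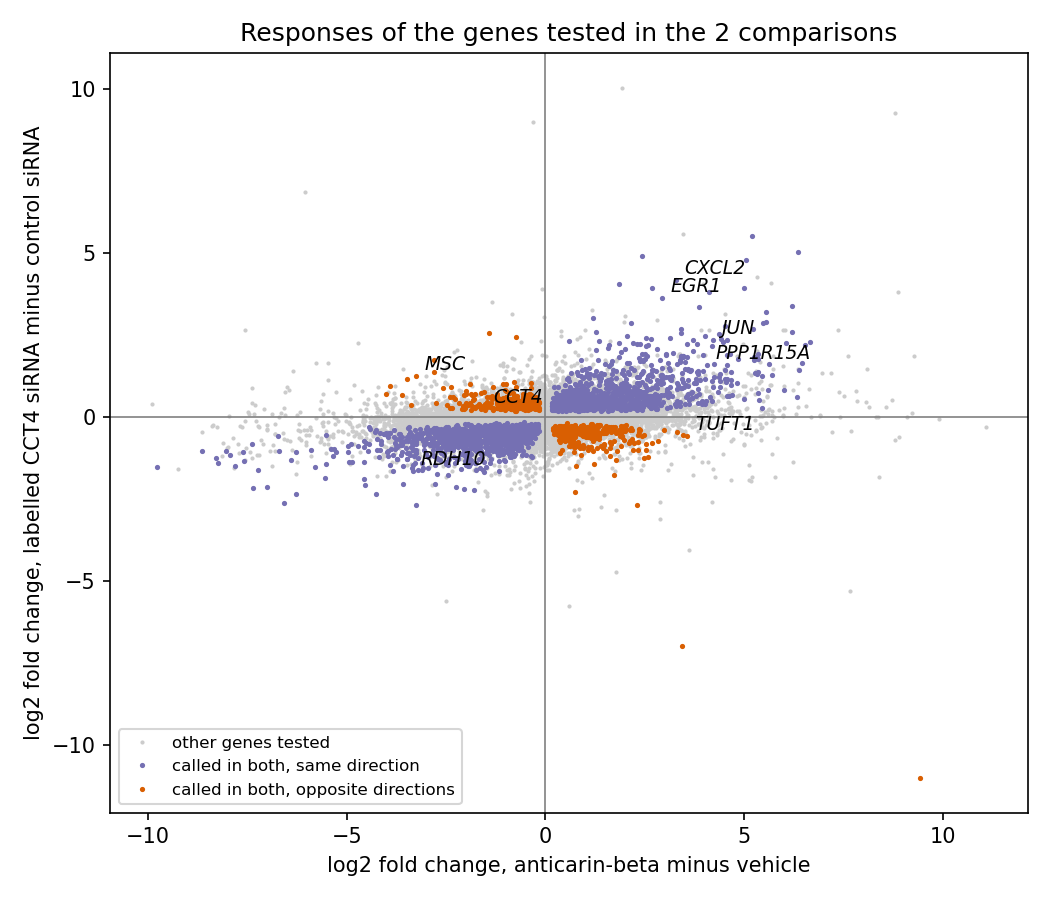
Log2 fold change with anticarin-beta (x axis) against that in the libraries labelled CCT4 siRNA (y axis) for the 17717 genes tested; each point is a gene, purple where called in both in the same direction (2242 genes) and orange where called in opposite directions (659 genes). CCT4 lies at −1.52 and 0.22, and CXCL2 at 3.28 and 4.16.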

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

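The tests of a swap of the siRNA groups, of an unstable CCT4 count and of a lower CCT4 level in both experiments, and the splits within the 2 experiments, were chosen after the results they bear on were seen.

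CCT4 mRNA stood out because its change differed between the 2 experiments, by −1.74 on the log2 scale: it fell with anticarin-beta and did not fall in the libraries labelled CCT4 siRNA. An exchange with the anticarin-beta libraries is argued against, since 3 of 3 libraries labelled CCT4 siRNA were nearer to every control siRNA library than to any vehicle library. An unstable count at CCT4 is argued against by its highest over lowest level of 1.16 within the siRNA groups. A swap of the siRNA groups stays open, since a weak knockdown would then leave CCT4 slightly higher in the libraries labelled CCT4 siRNA. The interval of the log2 fold change lay above 0 under TMM scaling, but its lowest lower bound over 4 scalings was −0.13. What also stays open, untested here, is a transfection that did not lower CCT4 mRNA or had recovered by 2 days, or a depletion at the protein level.

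DNA replication genes and proteasome subunits stood out because their lists passed in opposite directions in the 2 comparisons and the difference itself was called. Their median differences of log2 fold changes were −2.03 and −0.83. With an estimated correlation the DNA replication increase in the libraries labelled CCT4 siRNA was lost (adjusted p = 0.156). For the proteasome the compound's decrease (adjusted p = 0.509), the increase in the labelled libraries (adjusted p = 0.216) and the difference (adjusted p = 0.289) were all lost.

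Same-direction changes outnumbered those of independent lists. GC content or transcript length bias is argued against, since the correlation across genes was 0.33 after both trends were removed. Lower CCT4 mRNA in both treated groups is argued against for a decrease of the size seen with anticarin-beta. In the libraries labelled CCT4 siRNA its log2 fold change was above 0 under each of 4 scalings (0.09 to 0.22). The interval lay above 0 under TMM scaling (0.013 to 0.425) and RLE scaling (0.007 to 0.416). Its lower bound was −0.013 under upper-quartile scaling and −0.13 with library totals alone. The latter leaves room for a decrease of up to 8.46%, so a small shared decrease stays open. A shared stress or inflammatory response to any treatment stays open and was not tested.

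Other splits of the samples bear on the counts of genes called. For anticarin-beta the real grouping called 12926 genes and the highest of the other 9 splits of the 6 libraries 1; for the libraries labelled CCT4 siRNA these were 3493 and 3. In both, 10 splits are too few for a share under 0.05. For the difference between the responses, 2 of 100 splits drawn from the 200 within the 2 experiments reached the real 10610 genes, the highest other being 11913, with the siRNA groups exchanged. The 12 splits that kept the real compound groups called 9828 to 11913 genes and the others at most 1. The compound groups thus fix this number, and their 10 splits are too few for a share under 0.05. For same-direction genes the real grouping gave 2242 and the highest other 659, with the same exchange. That number cannot exceed the genes called in either comparison, so the 10 splits of each experiment are too few here as well for a share under 0.05.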

How the results depend on the processing

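The alternatives without mitochondrially encoded genes, without genes of unstable counts and with GC and length trends removed were chosen after seeing the data. CCT4 was lower with anticarin-beta under every alternative run (log2 fold change −1.94 to −1.44). In the libraries labelled CCT4 siRNA it missed the threshold under each (0.09 to 0.25), with adjustment over all genes tested. Adjusted over the CCT subunits alone, it passed as higher in those libraries under TMM scaling. Above a 2-fold change 8101 and 543 genes were called for the compound and the libraries labelled CCT4 siRNA, since this asks for more. Leaving out 1 library gave 2202 to 4026 genes in the libraries labelled CCT4 siRNA and 1480 to 2524 shared in direction, against 1011 at adjusted p under 0.01. Without a low-count filter, which added many sparse genes, the correlation was 0.14. With an estimated correlation 8 lists passed in the libraries labelled CCT4 siRNA and 4 for the difference. With library totals alone the compound's change reversed in CCT5 (−0.029), RPL30 (−0.13), HMGCS1 (−0.11), COL3A1 (−0.022), COL1A1 (−0.00672), PFN1 (−0.025) and TPM2 (−0.12), where the shift of the median by scaling is larger than these changes. Of the other values compared, 6864 kept their side of the threshold, 236 lost the threshold and 19 gained it. For genes the direction had to be kept as well, whereas lists were compared by their adjusted p alone. Named genes not called in a comparison were left out of this count, apart from DDIT3, CDKN1A and CCT subunits other than CCT6B. Deviations of same-numbered libraries correlated at only −0.03 to 0.03. In the compound experiment 0 of 3 numbers matched best with their own, so no pairing was seen there. In the siRNA experiment 3 of 3 did, a weak hint of pairing from the data only. With a replicate block 12637, 2350 and 10125 genes were called for the compound, the libraries labelled CCT4 siRNA and the difference, and 1544 shared in direction. For the compound the block brought the CCT subunit, STAT3, interferon-stimulated and osteoblast lists just under the threshold (camera adjusted p = 0.0450 each). It did the same for the interferon-stimulated list in the difference (camera adjusted p = 0.0473). Genes under about 3 counts per group cannot be ranked at this depth.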

Other observations

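The test of shared exons was chosen after its result was seen.

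Several gene groups held more lower than higher members with anticarin-beta without passing as lists. Of 22 cholesterol synthesis genes 14 were lower and 6 higher, or 14 and 7 adjusted over the list alone (median −0.74, adjusted p = 0.12), with MVK, mevalonate kinase, 11.3-fold and ACAT2 4.06-fold lower. Of 30 interferon-stimulated genes 17 were lower and 5 higher, also when adjusted over the list alone (median −0.49, adjusted p = 0.088); CMPK2 was 6.48-fold and MX1 4.74-fold lower. Of 20 NRF2 targets 13 were lower and 7 higher, also when adjusted over the list alone (median −0.39, adjusted p = 0.21), with GCLM, a glutathione synthesis gene, 4.30-fold lower. Of 15 tubulin genes 7 were lower and 3 higher, also when adjusted over the list alone (median −0.23, adjusted p = 0.205); TUBB was 3.64-fold lower and TUBG1 fell by 2.70 on the log2 scale. In these 4 lists 15, 23, 13 and 9 genes were lower and 4, 2, 5 and 0 higher with library totals alone.

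Of 12 osteoblast genes 7 were higher and 1 lower with the compound, also when adjusted over the list alone (median 0.32, adjusted p = 0.088, with a median of −0.10, 5 higher and 4 lower under library totals alone); BMP4 rose 24.1-fold. Of 18 STAT3 targets 10 were higher and 3 lower, or 10 and 4 adjusted over the list alone (adjusted p = 0.0655), and 9 and 7 with library totals alone, while SOCS3 was 2.31-fold lower. Ribosomal protein genes divided, 22 of 59 higher and 12 lower, or 19 and 11 adjusted over the list alone (median 0.14, adjusted p = 0.644), and with library totals alone the median was −0.27, with 2 higher and 35 lower. Hypoxia and glycolysis (7 of 26 higher, 8 lower; 6 and 6 adjusted over the list alone), ubiquitin and clearance (10 of 18 and 5), prefoldin (7 of 14 and 5), actin (9 of 19 and 5) and ribosome biogenesis genes (13 of 27 and 10) had adjusted p = 0.979, 0.549, 0.830, 0.384 and 0.407, the last 4 with the same counts adjusted over the list alone. These 5 lists turned towards lower levels with library totals alone, with 2, 8, 2, 5 and 10 genes higher and 15, 7, 7, 6 and 13 lower.

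Markers of other cell types reached a testable level in part, with 7 of 17 epithelial, 5 of 17 blood and immune and 7 of 11 endothelial markers tested. With the compound 1, 3 and 4 of these were higher and 3, 1 and 2 lower, the same adjusted over the list alone (adjusted p = 0.722, 0.830 and 0.878), and in the libraries labelled CCT4 siRNA the lists had adjusted p = 0.185, 0.915 and 0.344. Under library totals alone 0, 1 and 2 were higher and 4, 1 and 3 lower with the compound. In the libraries labelled CCT4 siRNA, HSF1 genes (5 of 24 higher, 1 lower), p53 targets (5 of 23 and 2; 6 and 2 adjusted over the list alone), ER chaperones (6 of 22 and 2; 7 and 2), NRF2 targets (4 of 20 and 0), ubiquitin genes (5 of 18 and 2; 5 and 3), interferon-stimulated genes (5 of 30 and 5; 5 and 6), ribosome biogenesis genes (2 of 27 and 2) and mitosis genes (2 of 30 and 0; 0 and 0) did not pass as lists, with adjusted p = 0.135, 0.0798, 0.174, 0.165, 0.119, 0.616, 0.915 and 0.997. The balance of these 8 lists moved down under library totals alone, with 0, 4, 1, 1, 4, 1, 1 and 0 genes higher and 3, 4, 3, 2, 4, 8, 2 and 2 lower.

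A set of abundant genes had counts that jumped between replicates. In 169 genes with a mean of at least 500 counts, the highest library of a group was more than 2.5 times the lowest in at least 1 group; they include B2M, which ranged from 2976 to 12330 counts among the vehicle libraries, and were singled out after their values were seen. Sampling noise alone is argued against, because Poisson draws gave 0 such genes, as is 1 deviating culture per group, because no library held more than 39.6% of them. Poisson draws could hardly give such a range at 500 counts, and replicates differed by more than sampling noise across all genes. Whether that wider spread between replicates would give as many such genes was not tested. Reads shared with an overlapping gene on the same strand may contribute, since 27.8% of the 90 such genes abundant in all groups have such an overlap against 15.9% of the others, but that leaves most without one. Of these 90, 35 jumped in 2 or more groups, against 1.80 expected, so a cause tied to the gene, such as the counting step, stays open and was not tested.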
